A study of Mus musculus with 8 samples.

How the data were processed

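RNA was measured in single bone marrow progenitor cells from wild type mice and from mice heterozygous for Mof (Kat8). Per the labels' protocols, sorted cells were frozen and their RNA was made into CEL-Seq2 libraries. The labels give 8 libraries, 2 in each of 4 groups, namely HSC and plate2 libraries of each genotype. The deposited values are expected counts, that is, estimated counts of transcripts per gene and barcode that are not scaled for depth. Each value equals 4096 times the negative natural log of 1 - k/4096 for a whole number k of distinct molecular identifiers, with a largest deviation of 3.6e-12. BWA 0.6.2-r126 and the mm10 build are named per the submitters' processing notes. The gene annotation, the read filters and the counting tool are not given in the sources used here.

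The 8 library files together held 1536 barcodes and 19879 gene names, besides 70 spike-in rows that stayed out of library sizes and tests. The share of rows naming no gene was 0%. Values were rounded to whole numbers before edgeR. Gene coordinates came from GENCODE vM21 (GRCm38), which held 19011 of the 19879 names (95.6%). A barcode was kept as a cell with at least 1000 transcripts over named genes, which left 436 cells. No doublet caller was run, since cells were sorted into wells. Kept libraries held from 99253 transcripts in wild type HSC library 1 to 733925 in wild type plate2 library 1. Between the 2 libraries of a group, genes with at least 20 transcripts gave a chi-square per degree of freedom from 2.20 to 4.47, where counting error alone gives 1.

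Counts were summed over the kept cells of each library and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood fit and two-sided test). Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p values of single genes are from edgeR throughout. A one-way layout of the 4 groups gave the genotype effect in each plate set, the difference of these effects, and plate2 against HSC libraries in each genotype. The effect over both sets used all 8 libraries with plate set as a term. Within cell classes, counts were summed per class and library over libraries with at least 10 cells of the class. CPM are given without TMM factors, and SE are those of the fitted log2 fold change. A bound on a fold sets a group without counts to 3 counts.

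Lists of genes, 40 in number, were fixed before the data were examined and covered cell types, chromatin regulators, signalling, cell cycle, metabolism, translation and quality checks. Of these, 35 had at least 3 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over lists), and beside it with camera with an estimated correlation and with fry. Genes named in the text followed a rule fixed at the same time. Kat8 is always named. For each comparison the rule takes the 10 genes of largest rise and the 10 of largest fall that passed, were separated between all libraries of the groups and had a mean of at least 20 CPM, leaving out predicted models. Where fewer than 5 passed on a side, the 5 of smallest p are named and said not to pass. The rule adds up to 4 members of each list that passed, of which the text gives examples, and for cell classes it takes 5 genes per side. Values of some genes that the rule names are not reported here.

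Kept cells were clustered with scanpy 1.11.5 and igraph 0.11.9 in Python 3.11.15 (2000 variable genes, 15 principal components, 15 neighbours, Leiden resolution 1, a fixed seed). Thinning of cells to 1000 transcripts used seed 1. A cluster was named after a cell type when at least 3 markers of that type, and more than of any other type, were among its 50 leading genes and detected in at least 50% of its cells. Shares of classes carry exact Clopper-Pearson intervals, and shares and library medians were compared by exact two-sided permutation of genotype labels. Other tools were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9. The edgeR fit was tested on simulated data, in which it recovered 17% of genes changed by 2-fold and 84% of those changed by 4-fold in the plate2 comparison. Simulated counts used each gene's mean over all 8 libraries and the dispersion trend, without levels of a plate set or single wells.

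Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, at least 2000 transcripts per cell, all barcodes, each cell thinned to 1000 transcripts, only the 4 libraries of a set, the mean of the sets, replicate number as a block, Leiden resolutions 0.5 and 2, 30 components, and leaving out each library. Alternatives added after seeing the data were own barcodes only, a screen on estimated carry-over under 20%, whole molecular identifiers, leaving out wells with at least 10 mature neutrophil transcripts, and library size alone.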

Results

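The series measured RNA in single mouse bone marrow progenitor cells with CEL-Seq2, a method that tags each captured transcript with a molecular identifier and counts identifiers per gene and well. Cells came from wild type mice and from mice with 1 functional copy of Mof. Mof is the older name of Kat8, which encodes a lysine acetyltransferase of histone tails and is the catalytic subunit of the MSL and NSL chromatin complexes. The comparison of the genotypes asks what losing 1 copy changes in these progenitors. The design text states 768 cells over 8 sort gates, from haematopoietic stem cells (HSC) through erythroid, granulocyte-monocyte and megakaryocyte progenitors. The labels name 8 libraries in 4 groups of 2. These are wild type HSC, heterozygous HSC, wild type plate2 and heterozygous plate2, and no label gives the gate of a plate2 well. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

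The libraries listed 1536 barcodes, and 436 of them held at least 1000 transcripts and were kept as cells. Of these, 206 were wild type and 230 heterozygous, and 305 reached 2000 transcripts. Kept cells summed to 99253 and 103010 transcripts in the wild type HSC libraries and to 244109 and 201017 in the heterozygous ones. The plate2 sums were 733925 and 424490 in wild type and 630053 and 677862 in heterozygotes. Each library held most of its transcripts in its own 96 barcodes, and between 2.29% and 13.6% lay in the other 96. Y-linked Ddx3y ran from 58.2 to 139.3 CPM, scaled to kept transcripts, and Xist from 0 to 2.36 CPM over the 8 libraries.

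**Figure D1:**
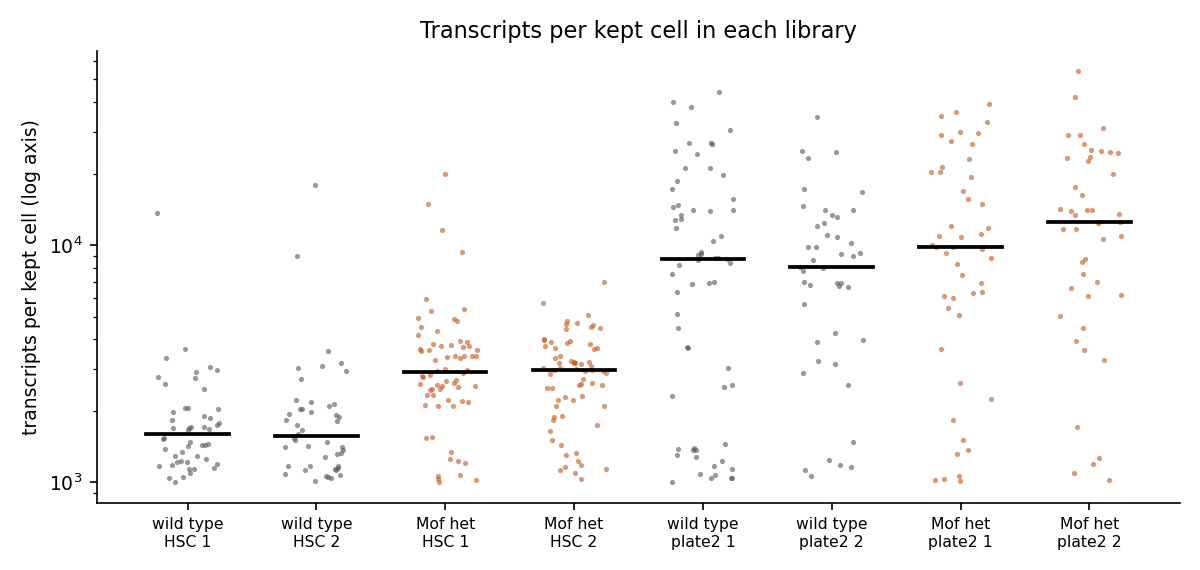
Transcripts per kept cell (log axis) in each of the 8 libraries, 1 point per cell, with the library median as a black line. Medians lay at 1600 and 1566.5 in the wild type HSC libraries, at 2921 and 2977 in the heterozygous HSC libraries, and between 8075 and 12515 in the plate2 libraries.

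Kat8 was caught in few cells of any library. Kat8 lies on chromosome 7 from 127912516 to 127925837 on the plus strand of GRCm38. The wild type HSC libraries held 1 and 2 Kat8 transcripts (10.1 and 19.4 CPM), and the heterozygous HSC libraries held 1 and 2 (4.10 and 9.95 CPM). The plate2 libraries held 10 and 4 in wild type (13.6 and 9.42 CPM) and 9 and 12 in heterozygotes (14.3 and 17.7 CPM). In the HSC libraries both genotypes summed to counts at the floor of 3, so no fold is given. In the plate2 libraries the fitted log2 fold change of heterozygous over wild type cells was 0.31 ± 0.63 (SE, n = 2 libraries per genotype). Over both sets it was 0.03 ± 0.55 (n = 4 per genotype), with a 95% interval from -1.05 to 1.11. Without the wild type plate2 library 2 or the heterozygous plate2 library 2 it stood at -0.16 and -0.18. The loss of 1 copy was therefore not detectable at this depth, and Kat8 cannot check the genotype labels. Across cell classes of wild type cells Kat8 did not pass either. Of the other members of the MOF complexes, none of 11 measured genes passed in either set, and camera gave the list an adjusted p of 0.873 in the HSC and 0.347 in the plate2 libraries.

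**Figure D2:**
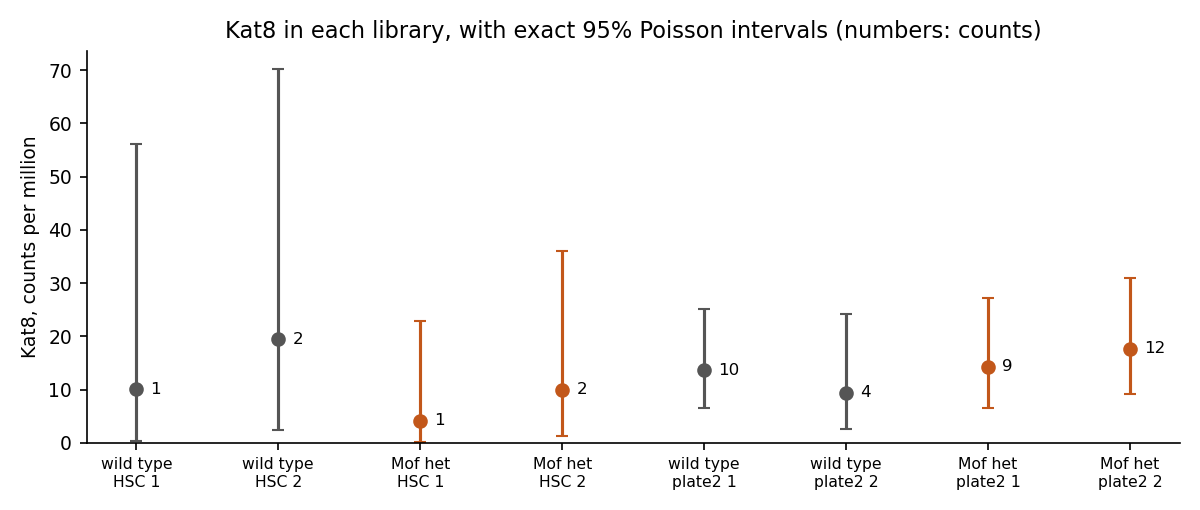
Kat8 in CPM of kept transcripts in each library, with exact 95% Poisson intervals of the count, which cover counting error only. Counts from 1 to 12 leave intervals that overlap between all 8 libraries.

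In the HSC libraries hardly any single gene passed, and cytosolic ribosomal protein genes stood higher in heterozygotes only as a list, by camera with its preset correlation. That call (camera adjusted p = 0.000466, and adjusted p = 0.955 with an estimated correlation) was also lost with fry (adjusted p = 0.468) and without wild type HSC library 2 (adjusted p = 0.179). Of 6690 genes tested, 1 rose and none fell at an adjusted p under 0.05. That gene was Gm17541, a processed pseudogene model on chromosome 12 (4689402 to 4689926, GRCm38), named after its values were seen. Its log2 fold change was 2.21 ± 0.36 (SE, n = 2 per genotype, adjusted p = 0.0266). Of the 74 measured ribosomal protein genes 53 had a positive log2 fold change, none passed over all genes, and 11 passed adjusted over the list alone. The examples of smallest p were Rps6 at 1.35 ± 0.25, Rpl17 at 1.71 ± 0.35, Rpl39 at 1.60 ± 0.38 and Rps19 at 1.79 ± 0.43. None of these reached an adjusted p under 0.05, Rps6 coming closest at 0.0616.

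Other genes at the head of the HSC comparison did not pass. Tmsb4x, which encodes an actin-binding thymosin, stood at 2.14 ± 0.47, the coactivator gene Pnrc2 at 2.78 ± 0.61 and B2m, the invariant chain of MHC class I, at 1.30 ± 0.29 (each adjusted p = 0.102). On the other side stood the small GTPase gene Hras at -2.44 ± 0.51, Zfp212 at -2.71 ± 0.57, the DNA ligase gene Lig3 at -2.84 ± 0.62 and Ccdc25 at -3.49 ± 0.78 (each adjusted p = 0.102), and Epn1 at -1.36 ± 0.32 (adjusted p = 0.135). At an unadjusted p under 0.05 stood 722 genes, where 334.5 are expected by chance. The fit shares 1 spread per gene over the 4 groups, and replicates lay further apart in HSC than in plate2 libraries. Chi-square per degree of freedom was 4.47 in wild type and 3.34 in heterozygous HSC, and 3.09 and 2.20 in plate2. HSC p-values can therefore be too small, and with only the 4 HSC libraries edgeR called 0 genes. DESeq2 called 30 genes and limma-voom 4. Without heterozygous HSC library 1 the edgeR count was 38, without wild type HSC library 1 it was 32, without wild type HSC library 2 it was 6, and without either heterozygous plate2 library it was 0. In simulated data of this layout and depth, the test recovered 6.5% of genes changed by 2-fold and 51% of genes changed by 4-fold. That simulation did not model HSC-specific levels, gene-wise spread or single wells, so recovery in the real HSC data can differ. Kept heterozygous HSC cells also had more transcripts per cell and more spike-in transcripts per cell.

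In the plate2 libraries, the genes that fell furthest in heterozygotes were those of mature neutrophils. Of the 10 measured mature neutrophil markers, 7 fell past the threshold over all genes and 9 adjusted over the list alone. Retnlg, which encodes a resistin-like peptide of granulocytes, had 242 counts over the wild type libraries and 0 over the heterozygous ones, so it was at least 91.1-fold lower against a floor of 3 counts over the group. Lcn2, the siderophore-binding lipocalin of granules, was at least 44.8-fold lower (0 counts in heterozygotes), and the granule protein gene Ngp at least 33.9-fold lower (90 against 0). Camp, the cathelicidin gene, was 38.8-fold lower (3 counts in heterozygotes), with a counting interval from 12.9 to 191.05. The collagenase gene Mmp8 fell by a log2 fold change of -4.95 ± 0.73 (SE, n = 2 per genotype, adjusted p = 0.00187) and the calprotectin subunit gene S100a9 by -4.68 ± 0.86 (adjusted p = 0.0123).

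The same libraries placed these transcripts in few wells. In the wild type plate2 libraries 6 of 110 kept wells held 98.5% of the 2798 transcripts of the mature neutrophil list. In heterozygotes 1 of 94 kept wells held 84.4% of 205. S100a6, a calcium-binding protein gene, fell by -2.67 ± 0.47 (adjusted p = 0.0101), and Lyz1, a lysozyme gene, by -2.15 ± 0.41 (adjusted p = 0.0143). Without wells holding at least 10 transcripts of the list, a setting chosen after seeing the data, S100a6 stood at -0.40 ± 0.63 and Lyz1 at -0.37 ± 0.34 (each adjusted p = 0.996). The mature neutrophil list was lower by camera (adjusted p = 8.9e-14, and adjusted p = 0.390 with an estimated correlation).

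Among genes that rose in heterozygous plate2 cells was Pf4, the platelet factor 4 chemokine of megakaryocytes and platelets, on chromosome 5 (90772435 to 90773383, GRCm38). Its log2 fold change was 2.58 ± 0.53 (adjusted p = 0.0225), from 5.45 and 21.2 CPM in wild type to 88.9 and 66.4 CPM in heterozygotes. Single wells held 53 of the 56 Pf4 transcripts of heterozygous library 1 and 36 of the 45 of library 2. Klhl32, which encodes a kelch-like protein and lies on chromosome 4 (24612554 to 24851124, GRCm38), rose by 2.10 ± 0.47 (adjusted p = 0.0394), from 29.98 and 32.98 CPM to 153.96 and 141.6 CPM. Leaving out any 1 of the 4 plate2 libraries ended both calls, with adjusted p from 0.0799 to 0.526 for Pf4 and from 0.414 to 0.563 for Klhl32. No well held more than 11 of the 97 and 10 of the 96 Klhl32 transcripts of those libraries. Next in line, but not passing, came the NADPH oxidase subunit gene Cyba at 1.47 ± 0.40 (adjusted p = 0.163), the metallothionein gene Mt2 at 1.54 ± 0.43 (adjusted p = 0.184) and Cox10 at 1.47 ± 0.45 (adjusted p = 0.304).

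**Figure D3:**
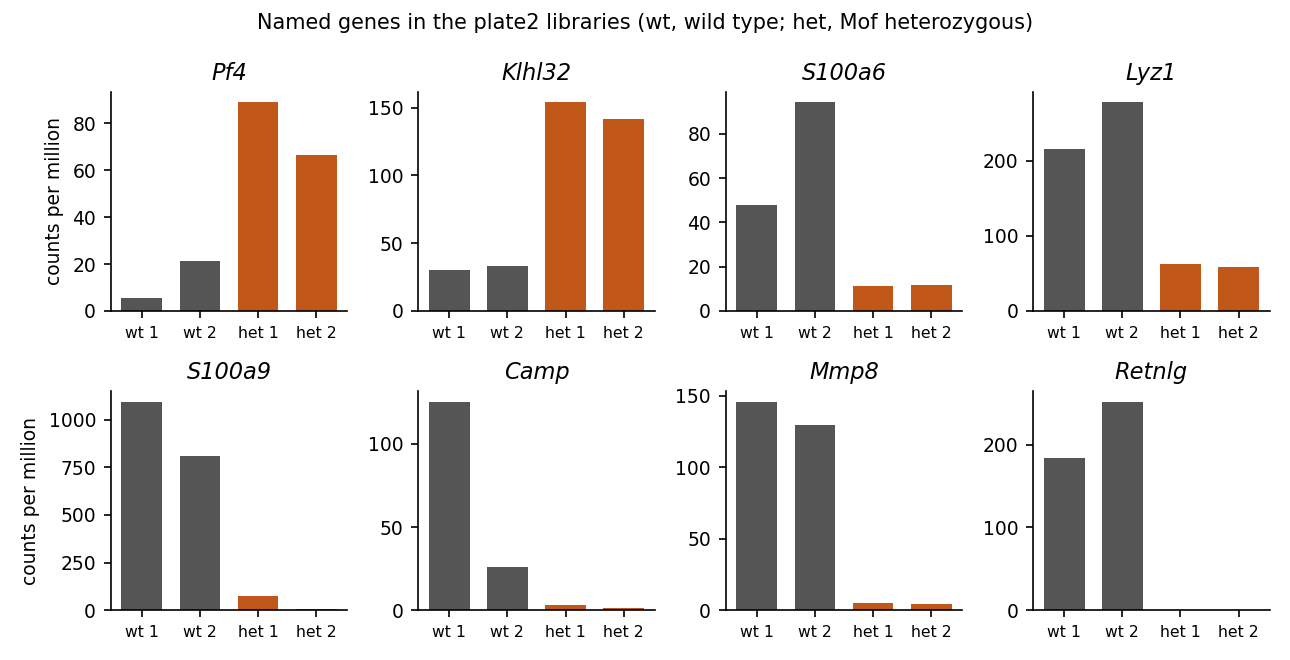
CPM of 8 named genes in the plate2 libraries, 1 bar per library, on axes that start at 0. Pf4 and Klhl32 were higher in both heterozygous libraries (Klhl32 at 153.96 and 141.6 against 29.98 and 32.98 CPM), and the other 6 genes lower in both.

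In all, 2 genes rose and 35 fell in the plate2 libraries, out of 6690 tested, and 26 of the 35 were predicted gene models. Gm10800, a repeat-like gene model on chromosome 2 (98666547 to 98667301, GRCm38) named after its values were seen, fell by -1.52 ± 0.22 (adjusted p = 0.00187). It took 9.60% and 12.6% of transcripts in the wild type libraries and 4.96% and 3.57% in the heterozygous ones. The 25 models named Gm and a number fell by between -1.67 and -1.27, and reads from such repeats can be shared between models. Leaving out heterozygous library 1 left 0 called genes, heterozygous library 2 left 2, wild type library 2 left 3 and wild type library 1 left 24, against 37. Leaving out an HSC library lets 8458 to 8584 genes through the count filter, and the count was 62 without wild type HSC library 1, 56 without wild type HSC library 2, 58 without heterozygous HSC library 1 and 57 without heterozygous HSC library 2. Thinning each cell to 1000 transcripts left 4.

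Other lists moved together in plate2 cells without single genes passing. The counts are sums over all kept cells. Changes within cell classes and changes in their mix cannot be told apart in any list tested on these sums. Erythroid progenitor-like cells, described below, held 699645 transcripts in 39 heterozygous cells and 350947 in 32 wild type cells of all libraries. Ribosomal protein genes were higher in heterozygotes, 73 of 74 positive (camera adjusted p = 3.4e-26, and adjusted p = 0.390 with an estimated correlation). Examples were Rplp1 at 0.75 ± 0.29 and Rpl41 at 0.66 ± 0.26. Nuclear genes of the respiratory chain were higher as well, 73 of 77 positive (adjusted p = 2.6e-13, and adjusted p = 0.390 with an estimated correlation), with Uqcr11 at 1.08 ± 0.35 and Cox5a at 0.60 ± 0.27. Ribosome biogenesis and MYC genes were positive in 22 of 25 (adjusted p = 0.00373, and adjusted p = 0.505 with an estimated correlation), with Cad at 0.56 ± 0.34 and Fbl at 0.41 ± 0.28. With each cell thinned to 1000 transcripts this list changed direction (camera adjusted p = 0.845). Neutrophil progenitor markers were positive in 7 of 9 (adjusted p = 3.6e-06, and adjusted p = 0.400 with an estimated correlation), and 1 passed adjusted over the list alone. These included the primary granule protease genes Prtn3 at 1.30 ± 0.40 and Elane at 1.497 ± 0.668. Wild type library 2 stood apart in these genes, with Elane at 2.36 CPM against 287.5 in wild type library 1 and 720.6 and 238.99 in heterozygotes, and Mpo at 16.5 against 991.9 CPM in wild type library 1. Without it Prtn3 stood at 0.66, Elane at 0.60 and the list at an adjusted p of 0.0844. A single well held 274 of 454 Elane and 323 of 583 Prtn3 transcripts of heterozygous library 1.

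Lower lists in heterozygous plate2 cells included stem cell markers, 12 of 13 negative (camera adjusted p = 3.2e-07, and adjusted p = 0.390 with an estimated correlation). Examples were Ctla2a at -0.91 ± 0.32, the endothelial receptor gene Tie1 at -1.24 ± 0.45 and the transcription factor gene Mecom at -0.98 ± 0.41. Late erythroid markers were negative in 8 of 8 (adjusted p = 0.000161, and adjusted p = 0.400 with an estimated correlation). The 3 globin genes measured were negative too (adjusted p = 0.0001, and adjusted p = 0.390 with an estimated correlation), all 3 passing adjusted over the list alone, Hbb-bs at -3.10 ± 0.98 and Hba-a1 at -2.70 ± 0.90. A single well held 526 of 643 Hbb-bs transcripts of wild type library 1 and another 94 of 95 of library 2. MHC genes were negative in 7 of 8 (adjusted p = 0.0114, and adjusted p = 0.463 with an estimated correlation), 1 passing adjusted over the list alone, with Cd74 at -1.50 ± 0.75. Immediate early and heat shock genes were negative in 12 of 15 (adjusted p = 0.0071, and adjusted p = 0.442 with an estimated correlation), with Egr1 at -1.16 ± 0.54. That list changed direction when each cell was thinned to 1000 transcripts (camera adjusted p = 0.845). Mitochondrially encoded genes were negative in 13 of 15 (adjusted p = 0.000484, and adjusted p = 0.390 with an estimated correlation). Their share of all transcripts was 14.7% and 14.8% in the wild type libraries and 13.4% and 15.2% in the heterozygous ones. By that share heterozygous library 2 lay above both wild type libraries. The list of RNA quality genes was negative in 4 of 4 (adjusted p = 0.00809, and adjusted p = 0.400 with an estimated correlation), Neat1 at -0.77 ± 0.36 and Malat1 at -0.50 ± 0.26.

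Over both plate sets, with the set as a term, the genotype effect came down to 1 gene that rose and 8 that fell among 6690. Pf4 rose by 2.42 ± 0.41 (SE, n = 4 per genotype, adjusted p = 0.0109). Outside the top well of each heterozygous library lay 38 and 19 Pf4 transcripts in HSC and 3 and 9 in plate2. Wild type libraries held 6 and 2 in HSC and 4 and 9 in plate2, all wells counted. S100a6 fell by -1.94 ± 0.36 (adjusted p = 0.0204), Mmp8 by -5.15 ± 0.63 (adjusted p = 0.000217), Retnlg by -4.94 ± 0.76 (adjusted p = 0.0047), the gelatinase gene Mmp9 by -5.18 ± 0.98 (adjusted p = 0.0243) and the globin gene Hbb-bs by -3.49 ± 0.71 (adjusted p = 0.0417). In only 5 of the 9 genes did the libraries of the genotypes stay apart in both sets. In the HSC set Mmp8 (292.2 and 0 CPM in wild type against 0 and 4.97 in heterozygotes) and Retnlg (251.9 and 0 against 4.10 and 44.8) had their wild type counts in library 1 alone, as did Mmp9 (40.3 and 0 against 0 and 4.97). A single well held 465 of the 509 Hbb-bs transcripts of wild type HSC library 1, while wild type HSC library 2 had 9 and the heterozygous HSC libraries 66 and 18, and without wild type HSC library 1 the gene stood at -2.03 (adjusted p = 0.524). The other 3 were the gene models Gm37903, Gm37746 and Gm37324, named after their values were seen. Without the neutrophil-marked wells 3 genes passed, and S100a6 stood at -0.21 ± 0.43. Leaving out heterozygous HSC library 2 gave 42 genes, wild type HSC library 2 gave 29 and wild type HSC library 1 gave 16. Without heterozygous plate2 library 1 the count was 1, without heterozygous HSC library 1 it was 2, without wild type plate2 library 2 it was 4 and without heterozygous plate2 library 2 it was 6, a range from 1 to 42.

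Genes next in line over both sets did not pass. They were the chaperone gene Hsp90b1 at 0.83 ± 0.24, Prtn3 at 1.14 ± 0.33, Rps18 at 0.79 ± 0.24 and Rplp1 at 0.74 ± 0.23 on the higher side. On the lower side were Nxpe2 at -1.46 ± 0.43, the lipid phosphatase gene Lpin1 at -1.43 ± 0.45, the prostaglandin receptor gene Ptger3 at -1.56 ± 0.51 and Tmem56 at -1.53 ± 0.51. Ribosomal protein genes were higher, 68 of 74 positive (camera adjusted p = 3.7e-18, and adjusted p = 0.516 with an estimated correlation). Respiratory chain genes were positive in 62 of 77 (adjusted p = 0.0102, and adjusted p = 0.864 with an estimated correlation), with Cox7c at 0.78 ± 0.32. Megakaryocyte markers were positive in 4 of 6 (adjusted p = 0.0376, and adjusted p = 0.516 with an estimated correlation), with Sdpr at 1.43 ± 0.48 beside Pf4. Neutrophil progenitor markers were positive in 7 of 9 (adjusted p = 0.0116, and adjusted p = 0.864 with an estimated correlation).

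Late erythroid markers were lower over both sets, 8 of 8 negative (camera adjusted p = 7.3e-05, and adjusted p = 0.516 with an estimated correlation), and globins in 3 of 3 (adjusted p = 0.000379, and adjusted p = 0.516 with an estimated correlation). Hba-a1 stood at -2.68 ± 0.63 and Hbb-bt at -1.80 ± 0.50, and both passed adjusted over the list alone. Single wells held 783 of 939 Hba-a1 transcripts of wild type HSC library 1 and 639 of 884 of wild type plate2 library 1, and 345 of 469 Hbb-bt transcripts of the latter. Wild type HSC library 2 (1097 and 203.9 CPM of the 2 genes) lay below heterozygous HSC library 1 (1163.4 and 253.98 CPM), and without wild type HSC library 1 they stood at -1.85 and -1.14. Mature neutrophil markers were negative in 10 of 10, 3 passing over all genes and 8 adjusted over the list alone (adjusted p = 0.0005, and adjusted p = 0.864 with an estimated correlation). Haem synthesis and iron genes were negative in 14 of 19 (adjusted p = 0.0402, and adjusted p = 0.864 with an estimated correlation). Stem cell markers were negative in 10 of 13 (adjusted p = 0.0376, and adjusted p = 0.864 with an estimated correlation), with Ifitm1 at -0.71 ± 0.23 and Hlf at -0.59 ± 0.23. Scaling by library size alone, chosen after seeing the data, moved the median log2 fold change of all genes to 0.117 in the HSC, 0.125 in the plate2 and 0.105 in the joint comparison.

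No gene passed the test of the difference between the genotype effects of the plate sets. At an unadjusted p under 0.05 stood 602 of 6690 genes against 334.5 expected, DESeq2 called 0 and limma-voom 1. That excess carries the same limit as the HSC one, a spread shared over the 4 groups. Klhl32 came closest on the higher side (3.18 ± 0.65, adjusted p = 0.208), ahead of Atad3a (2.36 ± 0.57), Mrpl45 (2.18 ± 0.54), Hras (2.68 ± 0.68) and the chaperonin gene Hspe1 (1.503 ± 0.390). On the lower side Camp had the smallest p (adjusted p = 0.208), ahead of Pnrc2 (-3.33 ± 0.70), Vmp1 (-2.95 ± 0.64), Gimap1 (-2.39 ± 0.54) and Alcam, a cell adhesion gene. Camp had 3 counts in heterozygous plate2 cells and Alcam 2 in wild type HSC cells, so no fold of either is given. Without heterozygous HSC library 1 the edgeR count was 37, without wild type HSC library 1 it was 12, without wild type HSC library 2 it was 3, and without either wild type plate2 library it was 1. By list, mature neutrophil markers stood lower in plate2 than in HSC cells in this difference (camera adjusted p = 0.000738, and adjusted p = 0.757 with an estimated correlation), 9 of 10 negative and 5 passing adjusted over the list alone. MHC genes were negative in 6 of 8 (adjusted p = 0.00287, and adjusted p = 0.757 with an estimated correlation), with B2m at -1.39 ± 0.40 and Cd74 at -3.58 ± 1.04. Respiratory chain genes were positive in 54 of 77 (adjusted p = 0.000738, and adjusted p = 0.757 with an estimated correlation), with Uqcrq at 1.55 ± 0.43. Without heterozygous HSC library 2 no list passed. The 2 sets' log2 fold changes had a Pearson r of 0.0307 across 6690 genes, which are not independent replicates.

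In wild type cells the plate2 libraries differed from the HSC libraries at 1188 of 6690 genes, 639 higher and 549 lower in plate2. Stem cell markers fell: 7 of 13 passed, all 7 downward, with the stem cell antigen gene Ly6a at -3.85 ± 0.42 (SE, n = 2 per group, adjusted p = 4.1e-06), Ctla2a at -2.69 ± 0.32, the interferon-induced membrane protein gene Ifitm1 at -2.54 ± 0.33 and Tie1 at -2.48 ± 0.41. The list was lower by camera (adjusted p = 1.9e-05, and adjusted p = 0.976 with an estimated correlation). Genes of S phase rose in 12 of 37 (adjusted p = 1.9e-05, and adjusted p = 0.976 with an estimated correlation), among them Nasp at 2.43 ± 0.53. Hells was 11.9-fold higher (2 counts in HSC cells, counting interval 3.22 to 99.03) and the ribonucleotide reductase gene Rrm2 13.3-fold (2 counts in HSC cells, interval 3.61 to 110.6). Genes of G2 and M phase rose in 5 of 37 and fell in 1 (adjusted p = 0.0113, and adjusted p = 0.976 with an estimated correlation), with Hmgb2 at 2.57 ± 0.33 and Kif20b at 2.64 ± 0.58. Ribosomal protein genes rose in 36 of 74 and fell in 6 (adjusted p = 2.5e-05, and adjusted p = 0.976 with an estimated correlation), with Rps19 at 3.49 ± 0.41 and Rpl34 at 3.04 ± 0.35.

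Several genes were at 0 in both wild type HSC libraries, whose sums were the smallest. Against a floor of 3 counts over the group, the neutrophil protease gene Ctsg was at least 12.7-fold higher in wild type plate2 cells, the ribosomal gene Rplp2 at least 11.5-fold, the succinate dehydrogenase gene Sdhd at least 6.46-fold, the initiation factor gene Eif2s3x at least 5.76-fold and the cell cycle factor gene E2f8 at least 5.01-fold. The Ctsg bound rests on wild type plate2 library 1, with 292.95 CPM against 7.07 in library 2, and without library 1 its adjusted p was 0.375. Usp17la, Chchd3, Pitrm1, Snhg6 and Ssr3 had bounds between 4.71 and 5.41-fold. On the lower side Cyp4v3 fell by -4.20 ± 0.60, Adam11 by -4.05 ± 0.70 and Acy3 by -3.89 ± 0.97. Vsig10l (9 counts in HSC against 1), Shroom4 (10 against 2), Clcn5 (13 against 3), Fam219a (9 against 2), Ctxn1 (10 against 3) and the endomucin gene Emcn (10 against 3) were lower by ratios of 51.5, 28.6, 24.8, 25.8, 19.1 and 19.1. The counting interval of Vsig10l ran from 7.14 to 2259 and that of Emcn from 4.92 to 107.95. Leaving out wild type HSC library 2, wild type plate2 library 1, wild type plate2 library 2 or wild type HSC library 1 left 437, 467, 736 and 761 called genes.

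In heterozygous cells the same comparison called 1482 of 6690 genes, 796 higher and 686 lower in plate2. Stem cell markers fell in 11 of 13 (camera adjusted p = 8e-11, and adjusted p = 0.465 with an estimated correlation), Ly6a at -4.22 ± 0.37 and Tie1 at -4.22 ± 0.39 (each n = 2 per group). Neutrophil progenitor markers rose in 6 of 9 (adjusted p = 0.00233, and adjusted p = 0.525 with an estimated correlation). The elastase gene Elane was at least 69.9-fold higher (616 counts against 0), Ctsg at least 57.2-fold (504 against 0), and the myeloperoxidase gene Mpo had 1770 counts against 1. The Mpo ratio of 602 had a counting interval from 107.98 to 23806. Ms4a3 was at least 8.74-fold higher, Slpi at least 6.13-fold, and the monocyte-associated genes F13a1 and Ly86 at least 16.7 and 6.47-fold. Ly6c2 (446 counts against 1) had a ratio of 151.8, with an interval from 27.1 to 6009. Rpl27 was at least 17.4-fold higher and Snhg6 38.1-fold (1 count in HSC cells, interval 6.70 to 1519). Erythroid progenitor markers rose in 3 of 13 and in 10 adjusted over the list alone (adjusted p = 0.000372, and adjusted p = 0.501 with an estimated correlation). These were the carbonic anhydrase gene Car1 at 2.93 ± 0.59, the aquaporin gene Aqp1 at 1.82 ± 0.44 and the erythropoietin receptor gene Epor at 1.99 ± 0.66.

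Cycling and growth genes stood higher in heterozygous plate2 than in heterozygous HSC cells. S phase genes rose in 23 of 37 (camera adjusted p = 8.4e-10, and adjusted p = 0.501 with an estimated correlation), with Hells at 3.70 ± 0.53 and Uhrf1 at 2.47 ± 0.45. G2 and M phase genes rose in 14 of 37 (adjusted p = 2.7e-06, and adjusted p = 0.501 with an estimated correlation), with Hmgb2 at 3.45 ± 0.32. DNA repair genes rose in 8 of 21 (adjusted p = 0.00271, and adjusted p = 0.501 with an estimated correlation), with the histone variant gene H2afx at 2.93 ± 0.57. Ribosome biogenesis genes rose in 12 of 25 (adjusted p = 1.1e-06, and adjusted p = 0.501 with an estimated correlation), Myc at 3.31 ± 0.43 and the nucleophosmin gene Npm1 at 1.03 ± 0.25. Ribosomal protein genes rose in 37 of 74 (adjusted p = 2.6e-10, and adjusted p = 0.501 with an estimated correlation), Rplp0 at 2.42 ± 0.31. Respiratory chain genes rose in 24 of 77 (adjusted p = 4.6e-08, and adjusted p = 0.501 with an estimated correlation), Cox5a at 2.54 ± 0.35.

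Interferon response genes fell in 11 of 19 in that comparison and rose in 2 (camera adjusted p = 0.000243, and adjusted p = 0.465 with an estimated correlation), Oasl2 at -3.49 ± 0.43 and Ifitm3 at -2.20 ± 0.33. MHC genes fell in 5 of 8 (adjusted p = 0.00259, and adjusted p = 0.501 with an estimated correlation), Cd74 at -4.17 ± 0.60 and H2-Ab1 at -3.00 ± 0.49. H2-Eb1, with 19 counts against 1, was 55.8-fold lower (counting interval 8.87 to 2320). Hox and partner genes fell in 5 of 8 (adjusted p = 0.00233, and adjusted p = 0.501 with an estimated correlation), Hoxa9 at -1.962 ± 0.355 and Meis1 at -1.995 ± 0.364. Immediate early genes fell in 8 of 15 and rose in 3 (adjusted p = 0.026, and adjusted p = 0.501 with an estimated correlation), Ier3 at -3.11 ± 0.51 and Egr1 at -2.46 ± 0.52. Mature neutrophil markers fell in 7 of 10 (adjusted p = 0.00559, and adjusted p = 0.710 with an estimated correlation). Ngp was at least 125.4-fold and Lcn2 at least 47.01-fold lower, and 3 heterozygous HSC wells held most of that list's transcripts there. Adam11 was at least 22.5-fold and Sgsm1 at least 18.6-fold lower. The low-count genes Camp, Gbp11, Ltf, Fam214b and Hist2h4 were lower by ratios of 88.1, 67.6, 58.8, 27.9 and 25.5, each with 1 to 3 counts in plate2. Their counting intervals began at 29.2, 10.97, 9.40, 6.73 and 7.80. Leaving out heterozygous plate2 library 2, heterozygous plate2 library 1 or heterozygous HSC library 2 left 488, 625 and 918 called genes.

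The wild type and heterozygous comparisons of plate2 with HSC libraries share no library. They shared 387 genes higher in plate2, where independent lists of those sizes share 76.03, and 266 genes lower, where 56.3 are expected. Across 6690 genes the log2 fold changes had a Pearson r of 0.662, and 1 gene was called in opposite directions. Plate set and sort gate cannot be told apart here, and the HSC libraries had fewer transcripts and far more spike-in transcripts per cell. With each cell thinned to 1000 transcripts, 305 of 986 genes passed in wild type and 227 of 986 in heterozygotes, with Ly6a at -3.59 and -3.80. With scaling by library size alone the wild type calls split into 457 higher and 797 lower (36.4% higher against 53.8%) and the heterozygous calls into 557 and 899 (38.3% against 53.7%), with the median of all genes at -0.161 and -0.156.

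Clustering of the 436 kept cells gave 10 clusters, of which 4 carried enough fixed markers for a name. The erythroid progenitor-like class joined clusters led by Car1, Ermap and Gata1 and by Car1 and Aqp1. The neutrophil progenitor-like class was led by 5 neutrophil progenitor and 3 monocyte markers among its top 10 genes. The late erythroid-like class was named on 5 late erythroid against 4 erythroid progenitor markers among its leading genes. Its top 10 genes held 1 marker of each. The number of markers a name needs was chosen after the clusters were seen, and cells in clusters without a name made up 92.7% of wild type HSC, 95.6% of heterozygous HSC, 60.9% of wild type plate2 and 44.7% of heterozygous plate2 cells. At the resolution of 1 and 15 components used here, stem cell markers named no cluster of the HSC libraries. At a resolution of 0.5 a stem cell-like class held 78% and 76.1% of the wild type and 80.9% and 77.9% of the heterozygous HSC cells per library. With 30 components it held 54% and 67.4% against 75% and 50%. At 2000 transcripts per cell it held 46.2% and 42.9% of only 13 and 14 wild type HSC cells. The heterozygous shares were then 77.2% and 67.3% of 57 and 52 cells. The exact permutation p was 0.3333, the smallest that 2 against 2 allows.

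**Figure D4:**
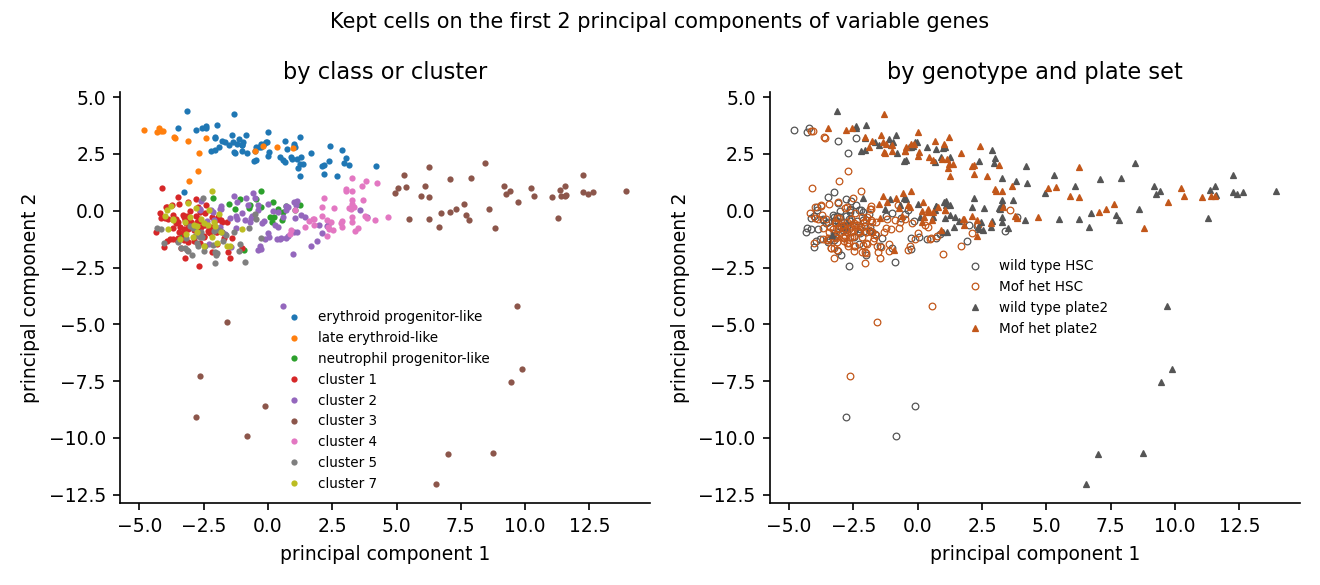
Kept cells on the first 2 principal components (unitless) of the variable genes, 1 point per cell, coloured by class or cluster on the left and by genotype and plate set on the right. The erythroid progenitor-like and late erythroid-like cells lie together at the top of component 2. Cells of both genotypes lie in each region but the lower right, where 6 wild type plate2 cells of cluster 3 lie.

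Within erythroid progenitor-like cells of the plate2 libraries, 3 genes rose in heterozygotes and none fell, out of 4669 tested. Of the cells summed, 13 of 31 wild type and 3 of 39 heterozygous ones lay outside the own barcodes of their library. For 10 of the 13 the deepest well of the same barcode was in a heterozygous library. With own barcodes only, chosen after seeing the data, cells were clustered and named anew, and 6 genes were called in the class of that name. Klhl32 rose by 2.76 ± 0.48 (SE, n = 2 per genotype, adjusted p = 0.000496). Vim, the intermediate filament gene vimentin on chromosome 2 (13573927 to 13582826, GRCm38), rose by 2.15 ± 0.39 (adjusted p = 0.000932). The gene model Gm43541 rose by 2.01 ± 0.31 (adjusted p = 7.7e-05) and is named after its values were seen. Genes that did not pass were Syt11 at 1.33 ± 0.33, Chchd10 at 1.73 ± 0.47 and the mitochondrial porin gene Vdac3 at 1.53 ± 0.43. On the other side stood Ccdc77 at -1.55 ± 0.48, Seh1l at -1.43 ± 0.45, Kif20b at -0.86 ± 0.28, Eif4ebp2 at -0.93 ± 0.30 and Tmem220 at -1.35 ± 0.44. Chance alone puts a share of 0.05 of the 4669 genes at an unadjusted p under 0.05, and the 252 found are close to that. At an unadjusted p under 0.05 stood 252 genes, and the count was 45 without wild type plate2 library 1, 6 without heterozygous plate2 library 2 and 2 without heterozygous plate2 library 1. Within cluster 1, which holds HSC cells of both genotypes, the ribosomal protein gene Rpl39 rose by 2.49 ± 0.54 (adjusted p = 0.045) among 916 genes tested. Below the threshold there were Rpl17 at 1.61 ± 0.36, B2m at 1.20 ± 0.33, Txnip at 1.63 ± 0.46, the mitochondrial oxidase gene mt-Co1 at 0.91 ± 0.26, Zfp729b at -2.73 ± 0.75 and Gbp7 at -1.36 ± 0.38. The 3 globin genes called in cluster 1 are among its defining genes and are left out. Without wild type HSC library 1 cluster 1 had 20 called genes, against 4.

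Erythroid progenitor-like cells made up a larger share of heterozygous than of wild type plate2 cells. The share was 41.5% ± 0.256 (SD, n = 2 libraries) against 27.6% ± 4.47. Per library it was 20 of 48 and 19 of 46 in heterozygotes (exact Clopper-Pearson intervals 27.6% to 56.8% and 26.998% to 56.8%) and 20 of 65 and 11 of 45 in wild type (19.9% to 43.4% and 12.9% to 39.5%). The exact two-sided permutation p was 0.3333, the smallest that 2 against 2 allows. Of the 42 cells of the shallower erythroid cluster, 15 lay outside the own 96 barcodes of their library. Over the whole class in plate2 these were 13 of 31 wild type and 3 of 39 heterozygous cells. For 10 of the 13 the deepest well of the same barcode was in a heterozygous library, and all 13 such source wells were erythroid progenitor-like. On own barcodes alone, chosen after seeing the data, cells were clustered and named anew. The class there is therefore not the same cells less those wells. Its shares were 43.9% ± 5.53 in heterozygotes and 27.3% ± 0.671 in wild type, a difference of 16.6 percentage points against 13.9. It also took in a mean of 6.26% of wild type and 3.68% of heterozygous HSC cells. Cluster 3, in which Gm10800 took a median of 24.7% of transcripts, stood 12.4 percentage points lower in heterozygous plate2 cells (15.9% ± 7.05 against 28.3% ± 0.846, exact permutation p = 0.3333). Neutrophil progenitor-like cells made up 12.9% ± 6.40 of heterozygous and 6.92% ± 9.79 of wild type plate2 cells (exact permutation p = 0.667), with 0 of 45 in wild type library 2, for which the exact interval reaches 7.87%. Without that library the difference was -0.984 percentage points. Late erythroid-like cells made up 4.41% ± 4.16 of heterozygous and 6.26% ± 0.369 of wild type HSC cells (exact permutation p = 1), and without heterozygous HSC library 2 heterozygotes stood 1.09 percentage points higher. The sort gates can set all of these shares.

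**Figure D5:**
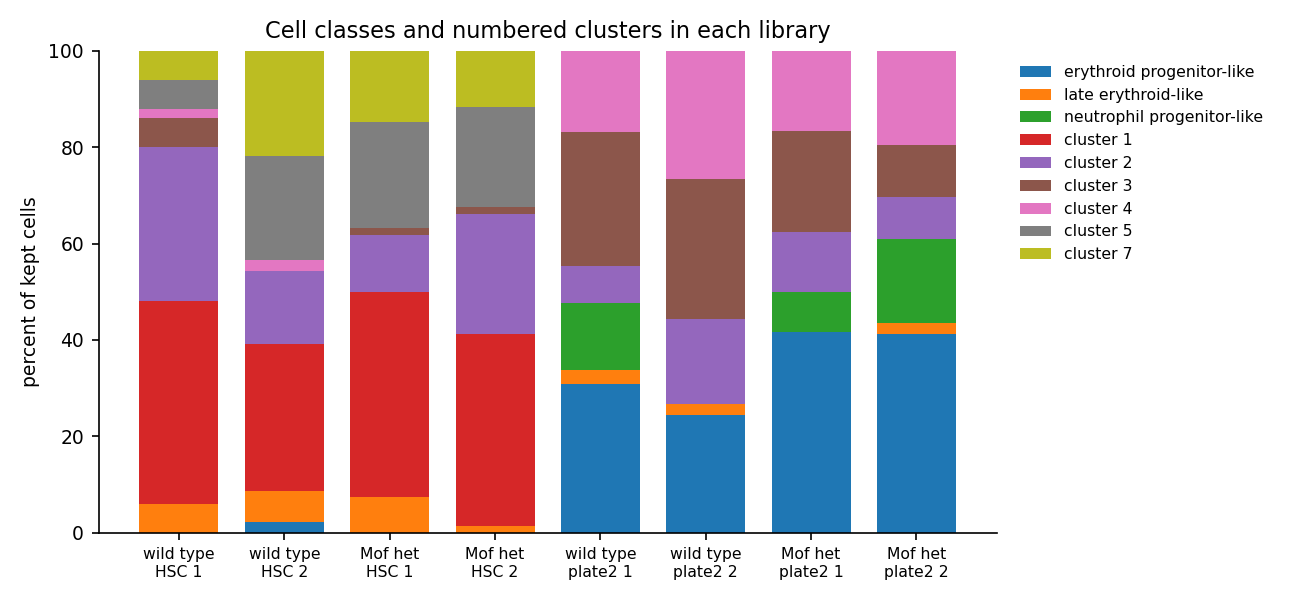
Percent of kept cells of each library in the named classes and the numbered clusters, as stacked bars that start at 0. Erythroid progenitor-like cells reach 41.7% and 41.3% in the heterozygous plate2 libraries and 30.8% and 24.4% in the wild type ones.

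Among cells kept at 1000 transcripts, those of heterozygotes held more transcripts than those of wild type in the same set. In the HSC libraries the library medians averaged 2949 ± 39.6 (SD, n = 2) against 1583 ± 23.7 transcripts, and in the plate2 libraries 11163 ± 1912 against 8397 ± 455. Permuting within sets gave an exact two-sided p of 0.0556, the smallest that 4 against 4 libraries allow. Kept plate2 wells outside the own barcodes were 11 of 65 and 4 of 45 in wild type, and 3 of 48 and 0 of 46 in heterozygotes. None of them held more than 1472 transcripts, so they can lower the wild type medians more. Medians on own barcodes alone are not given. Among cells with at least 2000 transcripts the HSC medians averaged 3283 ± 128.7 against 2814 ± 36.8, 1.17 times as many against 1.86 times at the lower minimum. The plate2 medians then averaged 12262.5 ± 1726 against 10482.5 ± 1853 and overlapped (11042 and 13483 against 11793 and 9172), with an exact permutation p of 0.667. Over both sets, with labels permuted within sets, the exact permutation p at this minimum was 0.3333. Over all barcodes of the plate2 libraries, with no minimum per cell, the difference was -76.25. Median spike-in transcripts per kept HSC cell were 268 ± 50.5 in heterozygotes and 133.2 ± 4.57 in wild type, 2.01 times as many, and 70.3% ± 0.736 against 50% ± 2.95 of own wells were kept. Transcripts per spike-in transcript were 11.3 ± 2.39 and 13.6 ± 1.17 in those libraries. In plate2 they were 869.1 ± 360.2 in heterozygotes and 569.4 ± 14.2 in wild type, 1.53 times as many, with 14.3 ± 5.31 and 15.01 ± 2.83 spike-in transcripts per cell. After thinning each cell to 1000 transcripts, heterozygous cells held 642 ± 5.66 genes in the HSC libraries against 592 ± 1.77, and 619 ± 2.47 in the plate2 libraries against 596 ± 1.41 (exact permutation p = 0.0556 within sets).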

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

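The tests of wells, carry-over and genes per cell at equal depth in this part were chosen only after the results were seen.

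The genotype effect differed between the plate sets for 7 gene lists by camera, and by none with an estimated correlation (smallest adjusted p = 0.757). In plate2 relative to HSC libraries, stem cell markers moved lower (camera adjusted p = 0.0252, 12 of 13 members negative), as did mature neutrophil markers (0.000738), cell cycle inhibitors (0.0306, 6 of 7) and MHC genes (0.00287). Erythroid progenitor markers (0.0365, 9 of 13 positive), respiratory chain genes (0.000738) and ribosome biogenesis and MYC genes (0.00826, 19 of 25) moved higher. The erythroid progenitor list changed direction without heterozygous HSC library 2. The stem cell list did so when each cell was thinned to 1000 transcripts (camera adjusted p = 0.855). Among members of the 7 lists Tie1 stood at -1.75 ± 0.57, Gfi1b at 1.963 ± 0.718 and Srm at 1.06 ± 0.45, none of which passed.

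Mature neutrophil genes were lower in the heterozygous plate2 libraries, and as wells with at least 10 transcripts of the list held 98.5% of them in wild type, the difference rests on 6 wells against 1, which is consistent with a few wells that each hold neutrophil RNA. Whether the genotypes differ in the number of such wells cannot be told apart from counting error, with a Fisher exact two-sided p = 0.127 for 6 of 110 against 1 of 94, and an exact p = 0.0606 when genotypes are compared within each of 16 barcode positions, to which positions without such wells add nothing. The 6 wells lie at position 8, where 7 wild type and 5 heterozygous wells were kept and none of those 5 was of this kind, and because the position was read from these wells the counts are given without a test. Gm10800 took 17.2% to 45.9% of the transcripts of the 6 wells and 1.44% of the heterozygous one, a neutrophil progenitor-like cell at position 9, while in the HSC libraries each genotype had 3 such wells, the wild type ones all in library 1. An effect of genotype on neutrophils, as the design would allow, stays open with 2 libraries per genotype.

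Of the 436 kept cells, 19 lay at barcodes outside their library's own 96. Barcodes outside the own 96 held transcripts that the comparisons otherwise leave out. Their share was 13.591% and 13.081% in the wild type HSC libraries, 8.119% and 8.890% in the heterozygous HSC libraries, 4.114% and 5.374% in wild type plate2 and 3.411% and 2.294% in heterozygous plate2. Of 543 such wells 519 (95.6%) had a profile most likely under the well of the same barcode in another library of the set, where chance gives 1 in 96, which fits carry-over between libraries. Free RNA spread evenly over barcodes is excluded as the only source. Well totals followed the same-barcode wells with a median Spearman rho of 0.879, against 0.0473 for the other plate set. An even addition leaves the ranks of wells unchanged, so rho cannot exclude it as a part. Each library shares its own 96 barcodes with a library of the other genotype in its set. Carry-over can therefore also mix genotypes inside the kept wells that all comparisons use. Transcripts at the outside barcodes came to between 1.52% and 6.54% of those of their source wells. No biological explanation was tested.

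Heterozygous cells held more genes per cell at equal depth in both sets. Fewer transcripts of Gm10800 and of mitochondrial genes are excluded as the whole cause in the HSC libraries, where without them, at 500 transcripts per cell, medians were 410 and 411 against 391 and 396 genes, a gap of 14 between the lowest heterozygous and highest wild type library (from 10 to 17.5 over 20 further draws). In the plate2 libraries that gap was 0 (401 and 405 against 401 and 400), against 13 with all transcripts (351 and 349 against 336 and 332), and it varied from -10.5 to 1 over 20 further draws, with -6.98 for the expected number of genes, so there fewer such transcripts could account for it. Gm10800 and mitochondrial genes were chosen because their shares were seen to differ. A genotype effect on the number of genes expressed stays open.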

How the results depend on the processing

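Own barcodes only, the carry-over screen, whole molecular identifiers, leaving out neutrophil-marked wells and library size alone were tests chosen only after the results were seen, and the other alternatives were fixed before the data were examined. Over all settings, 226 of 342 counts, shares and Kat8 values stayed within their limits, 11 reversed and the others moved. Of 691 values of lists 514 kept their side, 6 reversed and the others weakened, and of 4796 of named genes 4475 kept it, 11 reversed and the others kept their direction. Unless stated, the cause was not tested.

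The HSC count of 1 gene was 30 with DESeq2, 4 with limma-voom, 39 with no filter, 15 at 2000 transcripts per cell, 13 over all barcodes, 10 thinned, 2 without neutrophil wells, 3 with library size alone and 0 with only the 4 libraries of the set. The plate2 count of 37 was 75 with no filter, 4 thinned, 12 without neutrophil wells, 21 with library size alone and 64 with only the 4 libraries. The count of 9 over both sets was 20 with DESeq2, 31 with limma-voom, 64 with no filter, 15 over all barcodes, 5 thinned and 3 without neutrophil wells. The difference between sets, 0 in edgeR with 602 genes at an unadjusted p under 0.05, was 1 with limma-voom, 21 with no filter, 1 over all barcodes and 1 thinned. Plate2 against HSC in wild type, 1188 genes, gave 714 with DESeq2, 570 at 2000 transcripts per cell, 1829 over all barcodes and 305 thinned, and in heterozygotes, 1482 genes, gave 792 with DESeq2 and 227 thinned. Thinning left 986 genes to test against 6690, and no filter left 19756.

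Kat8 over both sets, 0.03, was -0.105 with DESeq2, -0.180 with limma-voom, -0.125 thinned, -0.000326 with the carry-over screen and -0.384 as the mean of the sets. Passing lists in the HSC comparison, 1, were 0 with an estimated correlation, 0 with fry, 4 with no filter, 10 at 2000 transcripts, 4 thinned and 3 without neutrophil wells. In plate2, 12 became 0, 0 and 4 with an estimated correlation, fry and thinning, over both sets 9 became 0, 0 and 4, and in the difference 7 became 0, 0 and 3. In wild type 4 became 0 with an estimated correlation, 0 with fry, 7 with no filter and 2 at 2000 transcripts, and in heterozygotes 14 became 0, 3 with fry and 7 thinned. Erythroid progenitor-like cells had 3 called genes, 5 at resolution 0.5 and 6 on own barcodes only, where cells were clustered and named anew. Over all barcodes, most of them below the minimum for a cell, the plate2 medians differed by -76.25 transcripts and -42.75 genes.

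Leaving out 1 library leaves an arm with 1, assumed to vary like the others. Counts then ran from 0 to 38 in HSC, 0 to 62 in plate2, 1 to 42 over both sets, 0 to 37 for the difference, 437 to 1373 in wild type, 488 to 1803 in heterozygotes, 2 to 45 in erythroid progenitor-like cells and 3 to 20 in cluster 1, and Kat8 over both sets from -0.182 to 0.228. Passing lists ran from 1 to 12, 9 to 16, 6 to 11, 0 to 15, 3 to 8 and 9 to 17 in the same order of the first 6. The neutrophil progenitor-like share difference ran from -0.984 to 12.9 and the late erythroid-like one from -4.79 to 1.09 percentage points.

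Genes that reversed were Hlf (0.00318) and Neat1 (0.133) in plate2 and Angpt1 (0.120) over both sets when thinned, and H2-Aa without wild type plate2 replicate 2 (range leaving out 1 library -2.85 to 0.858). Over both sets Plek was -0.0770 with limma-voom and -0.0532 without wild type HSC replicate 2 (range to 0.636), and Elane -0.0542 with DESeq2 and -1.21 as the mean of the sets. In the difference Ermap ran from -0.549 to 5.61 and Car1 from -0.107 to 4.29, both lowest without wild type HSC replicate 2, and Car1 was -0.00916 without heterozygous HSC replicate 2. Lists that reversed when thinned were immediate early genes (adjusted p = 0.845) and ribosome biogenesis (0.845) in plate2, respiratory chain (0.976) over both sets, stem cell markers (0.855) in the difference and immediate early genes (0.799) in heterozygotes. Erythroid progenitor markers reversed in the difference without heterozygous HSC replicate 2 (adjusted p from 5.6e-07 to 0.792).

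HSC libraries of the same number use the same 96 barcodes in both genotypes, and no label ties them by animal or batch, so no pairing was used in the tests. Deviations from the group mean correlated at r = -0.0898 over 6690 genes. With the number as a block the HSC count was 2, with only the 4 HSC libraries 4, and over both sets 5, and the block changed no other count by more than 1.5 times. At 2000 transcripts per cell the comparison within classes gave no value, and numbered clusters were not run under other clusterings. Simulated 2-fold changes were recovered in 6.5% of genes in HSC, 17% in plate2, 37% over both sets and 4% in plate2 against HSC in wild type.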

Other observations

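The tests of barcode position and of other splits in this part were chosen only after the results were seen, while the gene lists were fixed before the data were examined.

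Neither Pf4 nor Klhl32, the genes that rose in heterozygous plate2 cells, passed in the HSC libraries. There Pf4 had 6 and 2 transcripts in the wild type and 65 and 23 in the heterozygous libraries, found in 3, 1, 13 and 12 cells, with a log2 fold change of 2.20 ± 0.62 that did not pass (adjusted p = 0.213). Klhl32 had 75 and 14 transcripts in wild type HSC and 50 and 47 in heterozygous HSC cells, at -1.08 ± 0.44 (adjusted p = 0.399). That negative value rests on wild type HSC library 1 at 755.6 CPM, since wild type HSC library 2, at 135.9 CPM, lay below the heterozygous libraries at 204.8 and 233.8. Without neutrophil-marked wells Pf4 in plate2 stood at 2.61 (adjusted p = 0.0426) and Klhl32 at 2.13 (adjusted p = 0.0676).

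Of the 35 lists tested, 14 passed in no comparison, and 19 in no genotype comparison. Their smallest camera adjusted p values were 0.347 for MOF complexes, 0.236 for other histone acetyltransferases, 0.209 for histone deacetylases, 0.176 for apoptosis, 0.326 for p53 targets, 0.0782 for cytokine receptors and signalling, 0.0918 for glycolysis and 0.252 for fatty acid oxidation. Among cell type lists they were 0.0512 for lymphoid-primed progenitor markers and 0.553 for monocyte or dendritic markers. Erythroid and megakaryocyte transcription factors gave 0.347, myeloid and lymphoid transcription factors 0.302, sort markers 0.180 and sex-linked genes 0.603. The other 5 of the 40 lists had fewer than 3 measured members.

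Cell classes followed the order of barcodes. Among plate2 cells on own barcodes, all 14 cells at position 9 of 16 were neutrophil progenitor-like, 14 of 16 cells at position 4 were erythroid progenitor-like and 11 of 12 at position 8 belonged to cluster 3. Permuting classes within libraries over 20 layouts gave a smallest adjusted permutation p of 0.0004, the smallest that 10000 permutations can give here, which is consistent with cells of different gates at regular plate positions. The 6 neutrophil-marked wells of wild type plate2 all lie at position 8 of 16. In the HSC libraries, position modulo 16 gave an adjusted permutation p of 0.0020. No label gives the gate of a position, so gates are not named here.

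Exchanging libraries between the genotypes tested the 9 genes over both plate sets. Of the 34 splits of the 8 libraries into 4 and 4 used, 1 called as many genes, the real one. Part of the 34 splits are not balanced over the plate sets, unlike the real one, so they are no like reference for it. Exchange within sets alone allows no exact two-sided permutation p below 0.0556, so the splits cannot exclude chance. The highest other split called 8, and it keeps the plate2 libraries by genotype and exchanges wild type HSC library 2 with heterozygous HSC library 2. Exchanging wild type HSC library 2 with heterozygous HSC library 1 instead called 1.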
